A study of Mus musculus with 2 samples.

How the data were processed

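Total RNA from hearts of 2 female B6CASTF1/J mice, the first-generation hybrid of the C57BL/6J and CAST/EiJ inbred strains, was sequenced at an age of 36 days. Each library was made from 300 ng of RNA with an added set of ERCC spike-in RNAs, synthetic transcripts of known amount. Per the labels, the spike-in mix was the one used for stranded libraries from which ribosomal RNA had been reduced. RNA had been extracted with an animal tissue kit of Norgen, per the labels' protocols. The labels number the animals 3 (replicate 1) and 4 (replicate 2) and call the libraries biological replicates with separate biosamples, although both carry the same donor identifier. The replicates were treated as 2 animals. They form 1 group, and no group was available to set against it.

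The authors quantified each library against the mouse genome build mm10 with gene annotation M21, per the deposited description files. The programs and their versions are not given in the sources used here. The first quantification is a gene table and a transcript table made from alignments to the transcriptome, whose columns are those the program RSEM writes. It holds the deposited expected counts, which are estimated reads per gene with shared reads divided between genes, and which are not normalized. It also holds the authors' TPM values, transcript abundances that are scaled by effective length to the same sum in each library, and a posterior mean TPM. The FPKM column gives reads scaled to effective length and to the total of the library, per the file headers. The second quantification is a transcript table made from the reads and a transcript index, whose columns are those kallisto writes. Its deposited estimated counts and TPM values were summed here per gene through the gene annotation. The tables gave 55536 mouse genes, all of which were matched to a GENCODE M21 symbol, and 97 spike-in rows. A further 26248 rows named only by a number were left out of all comparisons. Both quantifications used a reference of the C57BL/6J strain, so reads from the CAST allele carry mismatches, and the effect of these on the counts was not measured.

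The first library held 39053339 and the second 38332179 expected counts in sum. At this depth, 3 counts, the limit that a count of 0 allows, correspond to 0.0772 and 0.0786 CPM of the mouse total. All intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules. Levels are given as the mean TPM ± SD over n = 2. A gene was called detected at a TPM of at least 1 in each library. Agreement between the libraries was measured across genes as Pearson's r of log2(TPM + 1) for genes with a mean TPM of at least 1.

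The libraries were compared gene by gene on expected counts rounded to whole numbers. An exact two-sided binomial test set the counts of each gene against effective library sizes from the TMM normalization of edgeR 4.0.16, with Benjamini-Hochberg adjustment over the genes with a summed count of at least 50. A gene was called at an adjusted p under 0.05 and an at least 2-fold ratio. Log2 ratios are of replicate 2 over replicate 1 with 0.5 added to each count, and their 95% intervals are exact. This test compares the reads of 2 libraries and not conditions. The common dispersion that edgeR estimated with both libraries in 1 group gave a biological coefficient of variation of 0.113. For each of 41 gene lists, the median log2 ratio was set against 10000 random lists of the same size drawn from 20 bins of mean expression. A list stood apart when its median lay below the 2.5th or above the 97.5th percentile, and only lists with at least 3 genes at a summed count of 50 were compared. This is a description of these libraries and gives no p.

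Gene lists, paralogue pairs, genes with known alternative transcripts and the rule for naming genes were fixed before the data were examined. Named were the 20 nuclear protein-coding genes and the 10 other genes with the highest mean TPM, and the 10 highest and 10 lowest log2 ratios among called genes. From each list up to 4 members were named: the highest, the lowest and those called. The rule also names the 26 pairs and 26 alternative transcript genes. Some genes under these rules are not named in the text and enter only its counts and medians. Where a list had more called members, all of them were named, a choice made after the values were seen. For 3 symbols held by 2 gene identifiers the identifier with the higher mean TPM was used. A symbol outside these rules is given with the words that it was chosen after its values were seen. The comparison was tested on counts simulated for 13745 genes, with 200 of them changed and with counting noise alone. It called 48 of 50 genes changed 3-fold, 50 of 50 changed 4-fold, 50 of 50 changed 8-fold, 1 of 50 changed 1.5-fold and 1 of 13545 unchanged genes. Of 100 simulated lists of 10 genes shifted by 0.3 on the log2 scale, 100 stood apart, as did 3 of 100 lists without a shift. No spread between animals and no genes that vary together were simulated, so these are not error rates for the data.

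Alternatives covered the TPM minimum, FPKM, posterior mean TPM, the second quantification, other pseudocounts and filters, scaling by DESeq2 1.42.0 size factors, total counts or spike-in counts, a lower fold threshold, an exact test with edgeR's common dispersion, and each library alone. Computation used R 4.3.3, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Coordinates are those of the M21 annotation on mm10, counted from 1.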

Results

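Total RNA-seq of whole heart tissue was available from 2 female B6CASTF1/J mice aged 36 days, which form a single group. The libraries held 39053339 (replicate 1) and 38332179 (replicate 2) expected counts. The design therefore gives the level of each gene in the heart of this hybrid and how far the 2 animals matched, and no contrast between conditions.

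Muscle and energy genes made up most of the 20 highest nuclear protein-coding genes. Myh6, the alpha myosin heavy chain of adult mouse heart (ENSMUSG00000040752.16, chromosome 14, 54941921 to 54966927), had the highest mean of these at 8639 ± 451 TPM (SD, n = 2, as for all levels below). The 3 haemoglobin genes below lay above it in replicate 1, as did Hba-a1, Myl2, Hbb-bs and Mb in the second quantification. It was followed among muscle genes by the ventricular light chain Myl2 (7415 ± 125), the oxygen store myoglobin Mb (6665 ± 285), cardiac actin Actc1 (4607 ± 414) and the calcium pump Atp2a2 (4443 ± 233). Tropomyosin Tpm1 (4189 ± 88.2), the light chain Myl3 (4092 ± 212) and the troponins Tnni3 (3909 ± 89.3), Tnnt2 (3142 ± 19.99) and Tnnc1 (2019.5 ± 85.9) came next, with the calcium pump regulator Pln at 2325 ± 40.2 TPM. Energy genes in the highest 20 were the ATP synthase subunit Atp5b (3375 ± 173), the fatty acid binding protein Fabp3 (2204 ± 53.5) and the ADP/ATP carrier Slc25a4 (1911 ± 104). They also included the cytochrome c oxidase subunits Cox6b1 (1755 ± 57.4) and Cox4i1 (1742 ± 103) and the glycolytic enzyme Gapdh (1698 ± 122). The haemoglobin genes Hbb-bs, Hba-a1 and Hba-a2 were also among the 20, at 8552 ± 6161, 7449.8 ± 5385 and 6907 ± 4876 TPM, with by far the widest spread between the animals. These 20 genes took 24.1% of the nuclear protein-coding TPM in replicate 1 and 20.04% in replicate 2.

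Outside the nuclear protein-coding genes, mitochondrial and structural RNAs were highest. The mitochondrial ribosomal RNA genes mt-Rnr2 (16S) and mt-Rnr1 (12S) stood at 129423 ± 9491 and 63677 ± 8443 TPM. The signal recognition particle RNAs Rn7s1 and Rn7s2 had identical values of 67829 ± 3643 TPM, and the transcription regulator Rn7sk had 16534 ± 2088. In the first quantification, mitochondrial messenger RNAs were led by mt-Co1 (34963 ± 576), mt-Co3 (18097 ± 827) and mt-Cytb (15248 ± 1293), subunits of the respiratory chain. In the second, mt-Atp6 (28873 ± 1110) followed mt-Co1, and mt-Co3 was at 11120 ± 409. The remaining 2 of the 10 highest were Gm28661 (29025 ± 1258; chromosome 1, 24614885 to 24615565) and Gm29216 (14943 ± 685), chromosome 1 pseudogenes of mitochondrial genes. The 4 such pseudogenes on chromosome 1 took 3.001 ± 0.274% of the counts. The second quantification gave mt-Co2, a neighbour of mt-Co1 in the mitochondrial genome, 2917 ± 38.5 TPM against 470.1 ± 111 in the first, and it gave Rn7s1, Rn7s2 and Rn7sk under 1 TPM each.

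By class, mitochondrial genes took 30.3 ± 1.801% of the counts and their ribosomal RNAs alone 19.7 ± 1.52%. Haemoglobin genes took 1.54% of the counts in replicate 1 and 0.493% in replicate 2. Spike-ins made up 0.532% and 0.427%, and the 10 genes with the highest TPM 30.3 ± 1.55%. In TPM, which divides by length, mitochondrial genes took 33.4 ± 2.34%, haemoglobin genes 2.401 ± 1.72%, spike-ins 0.763 ± 0.1098% and the 10 highest genes 45.8 ± 1.57%.

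In total, 12024 genes reached a TPM of 1 in both libraries, 11055 of them protein-coding. Across the 12364 genes with a mean TPM of at least 1, the libraries correlated with Pearson r = 0.986 and Spearman rho = 0.983, where genes are not independent replicates. For 93.9% of these genes the TPM values lay within 1.5-fold of each other.

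**Figure D1:**
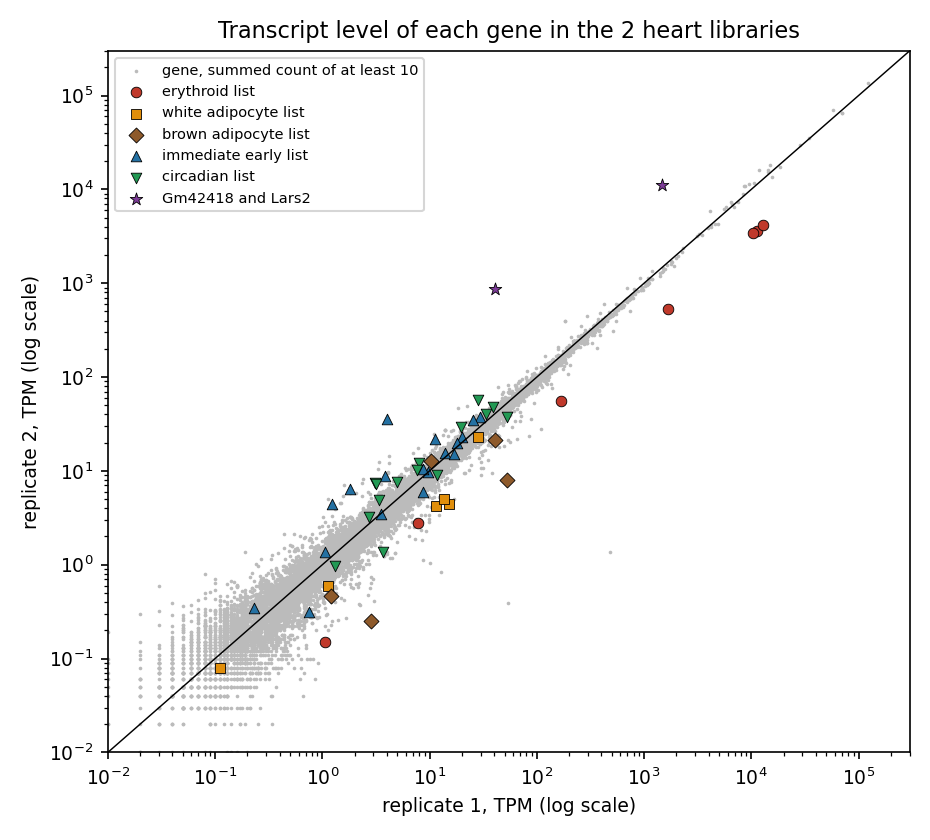
TPM of each gene with a summed count of at least 10 in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), where the line marks equal values and genes at 0 in either library are not drawn. Most genes lie on the line, haemoglobin genes of the erythroid list lie below it (12909 against 4196 TPM for Hbb-bs), and Gm42418 (1476 against 11174) and Lars2 lie above it.

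The gene families of the contractile apparatus and of metabolism were expressed mainly as their cardiac or adult forms. In all 26 fixed pairs of related genes the first-named, known cardiac or main heart form held over 50% of the pair's TPM in both libraries, and in 17 it held over 90%. Myh6 made 91.1% ± 0.0269 of the Myh6 and Myh7 total, Myh7 being the beta myosin heavy chain that prevails before birth in mice. Adult troponin I, Tnni3, made 99.986% ± 0.00023 against the fetal form Tnni1. Cardiac forms also prevailed for Tnnc1 against Tnnc2 (99.999% ± 0.00170), Tnnt2 against Tnnt1 (99.7% ± 0.0456) and cardiac actin Actc1 against skeletal Acta1 (91.9% ± 1.97). The ventricular light chains Myl2 and Myl3 made 96.6% ± 0.130 against atrial Myl7 and 93.5% ± 0.576 against atrial Myl4. Calcium genes showed the same order, with Atp2a2 against Atp2a1 at 99.992% ± 0.00169, Ryr2 against Ryr1 at 99.992% ± 0.000474, Casq2 against Casq1 at 99.1% ± 0.0386 and Pln against Sln at 98.6% ± 0.127. The connexin Gja1 made 95.6% ± 0.257 against Gja5, and the atrial peptide Nppa 94.2% ± 1.24 against Nppb.

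Among metabolic pairs, the muscle carnitine palmitoyltransferase Cpt1b made 87.8% ± 2.64 against the liver form Cpt1a, and the insulin-regulated glucose transporter Slc2a4 97.2% ± 0.289 against Slc2a1. Muscle forms led for creatine kinase Ckm against Ckb (97.9% ± 0.0437), enolase Eno3 against Eno1 (93.9% ± 1.27) and phosphoglycerate mutase Pgam2 against Pgam1 (88.2% ± 1.82). The muscle subunits Cox6a2, Cox7a1 and Cox8b of cytochrome c oxidase made 90.6% ± 1.53 against Cox6a1, 72.7% ± 0.817 against Cox7a2 and 86.5% ± 1.52 against Cox8a. Slc25a4 made 92.7% ± 0.592 against Slc25a5, and Fabp3 85.1% ± 0.0917 against Fabp4, a gene of endothelial cells and adipocytes. The balance was closer for hexokinase, Hk2 making 70.9% ± 0.930 against Hk1, and for lactate dehydrogenase, Ldhb making 77.1% ± 1.16 against Ldha. By expected counts and in the second quantification, 25 and 25 of the 26 first-named genes held over 50%.

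**Figure D2:**
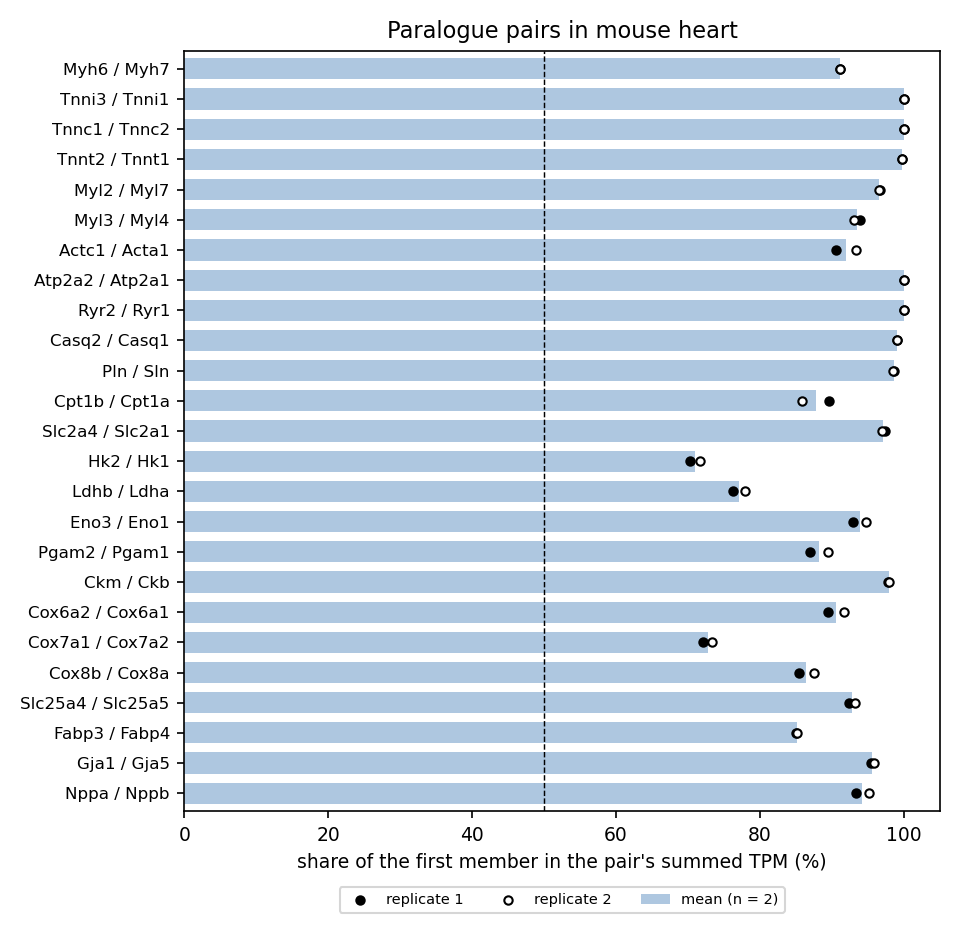
Share of the first-named gene in the summed TPM of each pair (x axis, percent), with bars for the mean of 2 libraries and points for each library. The first-named gene lies above 50% (dashed line) in each pair drawn, from 70.9% for Hk2 to nearly all of the pair for Tnnc1.

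Lists of heart function were almost fully detected. All 16 calcium handling genes reached a TPM of 1 in both libraries (median 126 TPM), from Atp2a2 down to the inositol trisphosphate receptor Itpr2 (8.63 ± 0.354). All 24 genes of fatty acid oxidation did so too (median 356), between Fabp3 and the nuclear receptor Ppara (18.6 ± 6.32). So did all 17 glycolysis genes (median 306.5), between Gapdh and Slc2a1 (4.34 ± 0.346), and all 22 nuclear-encoded respiratory chain genes (median 593), between Atp5b and cytochrome c, Cycs (62.7 ± 2.93). The 13 mitochondrially encoded proteins had a median of 9742 TPM, between mt-Co1 and mt-Co2. These levels depend on the quantification. The gene at the median, mt-Nd4l, chosen after its values were seen, was at 215 TPM in the second one, and mt-Co2 at 2917. Of the sarcomere list 25 of 26 were detected (median 714), the exception being fetal Tnni1 at 0.535 ± 0.0212. Of the ion channels and gap junction genes 20 of 21 were detected, with Gja1 highest (133 ± 6.92). Cardiac transcription factors numbered 15 of 16 (median 32.8), with Hopx highest (147 ± 0.856) and Hand1 at 0 counts in both libraries. The hypertrophic stress list was led by Myh7 (845 ± 46.9) and ended at the stress cytokine Gdf15 (0.215 ± 0.191), with 9 of 10 detected.

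The other functional lists had medians from 0 (Y-linked) to 57.7 TPM (heat shock). Cell cycle genes reached a median of 0.688 TPM with 6 of 18 detected, from the replication clamp Pcna (16.2 ± 0.686) to the checkpoint kinase Bub1 (0.170 ± 0.0141). Heat shock genes were all detected, from Hspa8 (479.9 ± 25.2) to Hspa1a (1.38 ± 0.219), and 6 of 10 of the interferon response genes were, with Oas1a lowest (0.305 ± 0.0495). Immediate early genes, which respond within minutes to stimuli, had a median of 9.62 with 16 of 18 detected, from Dusp1 (33.7 ± 5.68) to Egr3 (0.290 ± 0.0849). Circadian genes had a median of 8.94 with 14 of 15 detected, from Nr1d1 (45.2 ± 10.7) to Npas2 (1.14 ± 0.247). Of the imprinted genes 17 of 22 were detected, with Gnas highest (473 ± 44.3) and Dlk1 lowest (0.205 ± 0.219). Non-polyadenylated and nuclear RNAs, which total RNA libraries retain, ranged from Rn7sk to Rny3, which had no count in either library, with 8 of 10 detected. Xist, the RNA that coats the inactive X chromosome, was at 20.8 ± 1.05, and the X inactivation and escape list ran from Ddx3x (71.95 ± 4.82) to Tsix (0.310 ± 0.0424), with 6 of 8 detected. None of the 6 Y-linked genes was detected, their summed count being 1 in each library, which is under the limit of 3 counts; Ddx3y was listed at 0.00500 ± 0.00707 TPM and Kdm5d at 0.

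Cardiomyocyte markers had all 10 genes detected and a median of 955 TPM, from Myh6 to the ryanodine receptor Ryr2 (371 ± 21.7). Ventricular markers had a median of 81.8 (Myl2 highest, Hey2 lowest at 2.41 ± 0.255) and atrial markers 18.6 (Nppa highest at 662 ± 16.98). Conduction system markers were low, with a median of 1.83, between the connexin Gjc1 (11.2 ± 1.05) and the transcription factor Isl1 (0.135 ± 0.0778). Among other resident cells, medians were 43.8 for endothelial cells (Fabp4 386 ± 12.2, Tek 14.97 ± 0.198), 36.7 for fibroblasts (Gsn 343 ± 8.12, Tcf21 4.48 ± 0.0283) and 18.8 for smooth muscle (Acta2 56.9 ± 8.34, Cnn1 3.25 ± 0.856). Pericyte markers had a median of 12.4 (Rgs5 107 ± 5.28, Cspg4 6.11 ± 0.134), macrophage markers 9.57 (Lyz2 52.05 ± 1.88, Cx3cr1 1.30 ± 0.269) and lymphatic endothelial markers 5.47 (Prox1 19.6 ± 1.37, Mmrn1 2.495 ± 0.205). Mesothelial markers of the heart's outer lining had 3.50 (Upk3b 10.5 ± 0.346, Upk1b 2.54 ± 0.587). Every gene of these 7 lists was detected.

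Blood and fat genes were present, and most other tissues were near 0. Erythroid markers had a median of 1097 TPM, with Hbb-bs highest. White adipocyte markers had 8.64 (Cfd 25.8 ± 3.92, Lep 0.0950 ± 0.0212), and brown adipocyte markers 11.5 (Cidea 31.04 ± 13.8, Dio2 0.840 ± 0.523). Medians stayed under 1 TPM for T cells (0.0950; Cd4 0.245 ± 0.0212, Cd3g at 0), B cells (0.600; Ighm 3.82 ± 0.552, Ms4a1 0.175 ± 0.00707) and neutrophils (0.285; S100a8 0.955 ± 0.148, Ly6g at 0). The same held for mast cells (0.610; Tpsb2 0.965 ± 0.233, Ms4a2 0.0200 ± 0.0141) and Schwann and neuronal cells (0.510; Mbp 1.91 ± 0.212, Th at 0). Neighbouring tissues were as low: skeletal muscle (0.182; Tnni2 0.855 ± 0.403, Myh4 at 0), lung epithelium (0.00500; Sftpc 0.0250 ± 0.0354, Sftpd at 0) and thymocytes (0.00750; Cd1d1 1.51 ± 0.516, Dntt at 0). Hepatocyte markers had a median of 0.105, with Cyp2e1 at 5.74 ± 1.38 and Serpina1a at 0.

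**Figure D3:**
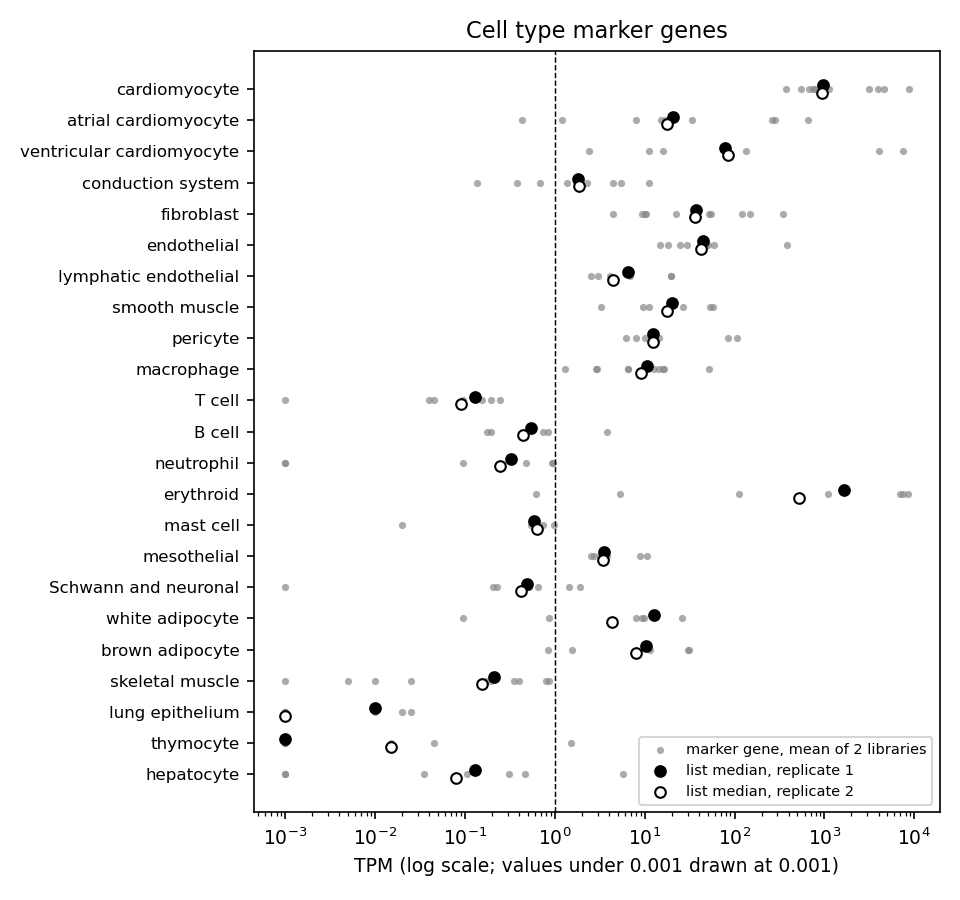
TPM of cell type marker genes (x axis, log scale), with grey points for the mean of each gene over 2 libraries and black and white points for the list median in replicates 1 and 2. Cardiomyocyte markers lie highest with erythroid markers, whose median was 1666 TPM in replicate 1 and 527 in replicate 2, and lung, thymus, liver, T cell and skeletal muscle medians lie below 1 (dashed line).

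For 17 of 26 genes with known alternative transcripts, both quantifications named the same leading transcript. A single transcript took nearly all TPM of the myosin binding protein Mybpc3 (Mybpc3-203, 99.5% ± 0.00254 of the gene's TPM in the first and 99.4% ± 0.128 in the second quantification). The same transcript also led with over 50% in both for Tpm1 (Tpm1-205, 96.96% ± 0.3999 and 72.01% ± 0.175), Actn2 (Actn2-201, 94.2% ± 3.28 and 82.2% ± 2.35) and Ryr2 (Ryr2-201, 85.3% ± 2.19 and 87.5% ± 1.39). Atp2a2 (Atp2a2-202, 76.6% ± 0.0382 and 82.8% ± 0.132), the Z-disc gene Ldb3 (Ldb3-203, 69.6% ± 1.42 and 69.5% ± 1.04) and Myom1 (Myom1-203, 56.97% ± 0.796 and 66.9% ± 3.74) completed these 7. In the other 10 genes the shared leader stayed under 50% in at least 1 of the quantifications. They included Ttn (Ttn-201, 36.4% ± 0.615), Camk2d (Camk2d-202, 48.5% ± 0.572), Mef2d (Mef2d-201, 53.4% ± 3.93), Pdlim5 (Pdlim5-205, 57.3% ± 0.293) and Nebl (Nebl-208, 32.1% ± 1.62), with percentages of the first quantification, and Kcnip2 (Kcnip2-202, 53.7% ± 4.999), Myh6 (Myh6-201, 42.96% ± 3.49), Vegfa (Vegfa-202, 33.01% ± 2.403) and Fhl1 (Fhl1-201, 75.2% ± 5.74). The leader of Nebl is annotated as a processed transcript and not as protein-coding.

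The quantifications named different leaders for 9 genes. Troponin T, Tnnt2, was led by Tnnt2-211 (65.5% ± 0.738) in the first and by Tnnt2-209 (39.1% ± 2.14) in the second. The pyruvate kinase Pkm was led by Pkm-202 (52.1% ± 1.26) or Pkm-201 (47.8% ± 0.820). The sodium-calcium exchanger Slc8a1 had Slc8a1-202 (41.95% ± 3.86) or Slc8a1-205 (42.3% ± 2.35), and the calcium channel Cacna1c had Cacna1c-218 (35.5% ± 0.896) or Cacna1c-212 (27.01% ± 0.150). For Gnas these were Gnas-206 (38.3% ± 1.18) and Gnas-207 (37.4% ± 0.403), and for Mef2c Mef2c-217 (20.1% ± 0.177) and Mef2c-201 (22.4% ± 0.987). Ank2 was led by Ank2-215 (26.7% ± 0.522) or Ank2-201 (30.4% ± 2.73). The leader of Cacna1c in the first quantification is annotated as a processed transcript.

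Between the 2 animals, red blood cell, fat, clock and immediate early genes differed most among the fixed lists. All 7 erythroid genes were lower in replicate 2, the haemoglobin gene Hbb-bs at 12909 TPM in replicate 1 and 4196 in replicate 2, with a log2 ratio of -1.56 (95% counting interval -1.57 to -1.55). Hba-a1 (-1.61), Hba-a2 (-1.53), Hbb-bt (-1.60), the haem synthesis enzyme Alas2 (-1.52) and the anion exchanger Slc4a1 (-1.94) were lower by similar or larger ratios. Ucp1, the uncoupling protein of brown fat (ENSMUSG00000031710.4, chromosome 8, 83290352 to 83298452), was at 52.6 and 7.95 TPM, a log2 ratio of -2.67 (95% counting interval -2.83 to -2.51). Nr4a1, an immediate early nuclear receptor (ENSMUSG00000023034.7, chromosome 15, 101254269 to 101274795), was at 4.01 and 35.5 TPM, a log2 ratio of 3.51 (95% counting interval 3.32 to 3.71).

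In all, 210 of 13745 genes were called by the exact binomial test at an at least 2-fold ratio, 75 higher and 135 lower in replicate 2. Of these, 135 (36 higher, 99 lower) were called in the same direction in the second quantification. At any fold, 2966 genes passed the adjusted threshold of this test, which allows for counting noise alone. The exact test with edgeR's common dispersion, which adds the spread between the animals, called 142 genes, and 216 at an unadjusted p under 0.05. That spread was estimated from the same 2 libraries, so it is not independent of the differences tested and cannot separate them from variation between animals. All calls compare the reads of 2 libraries, and their recurrence in other animals was not measured. With spike-in counts as the scale, which moved the median of all genes to 0.24, 167 genes were higher and 83 lower.

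Among the highest ratios in replicate 2, 3 genes with counts in both libraries were called in both quantifications. Lars2, encoding mitochondrial leucyl-tRNA synthetase (ENSMUSG00000035202.8, chromosome 9, 123366927 to 123462666), was at 40.9 and 875 TPM, a log2 ratio of 4.48 (95% counting interval 4.43 to 4.52). Nr4a1 followed, and then Gm42418, a long non-coding RNA gene on chromosome 17, 39846958 to 39848788, at 1476 and 11174 TPM and 2.98 (95% counting interval 2.97 to 2.99). The level of Lars2 depended on the quantification, with 4701 and 97483 counts in the first and 11314 and 283463 in the second. The other 7 of the 10 had under 1 count in replicate 1 and between 56.3 and 347.5 in replicate 2: 1700047I17Rik2, Gm14440, Gm20388, Ccl21b, Gm28539, Gm6565 and Rpl30-ps9. Of these, Gm28539 was called in the same direction in the second quantification and the other 6 were not, so no fold is given. 1700047I17Rik2 had a log2 ratio of -8.45 there and Gm20388 one of -0.33.

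Among the lowest ratios, Elovl3, a fatty acid elongase of brown fat, had 147 and 13 counts and a log2 ratio of -3.35 (95% counting interval -4.34 to -2.58). Of the 10 lowest, 7 were not called in the second quantification and are given as counts. They were Gm24497 (1394 and 3.87), Gm13370 (653 and 4.51), the ENSMUSG00000117748.1 entry of Chtf8 (250.0 and 11.2), the histone gene Hist1h2ah (124 and 7.76) and Gm6361 (106 and 10.7). Zfp969 had 80.98 and Gm10132 53 counts in replicate 1 and none in replicate 2. Gm24497 is annotated as a small nuclear RNA, as are Gm23444 and Gm23472, which were chosen after their values were seen. Gm23444 and Gm23472 rose, each with 529 counts in replicate 1 and 1095 in replicate 2. Whether reads were divided differently between these genes and Gm24497 was not tested, so its fall is not shown to be a change in level.

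By list, immediate early genes had a median log2 ratio of 0.42 over 18 genes, above the range of matched random lists (-0.10 to 0.09). Of these, 6 were called, and 6 adjusted over the list alone: Nr4a1, Atf3 (2.03), Nr4a3 (1.94), Fos (1.36) and Btg2 (1.02) higher, and Fosb (-1.19) lower. Fosb did not reach 2-fold with spike-in counts as the scale (-0.95) nor pass the exact test with common dispersion, and Btg2 did not reach it with total counts (0.95) or in the second quantification (0.98). Circadian genes had a median of 0.53 over 15 genes (range -0.10 to 0.09), and 4 were called, and 4 adjusted over the list alone. The clock outputs Dbp (1.09) and Ciart (1.52) and the period gene Per3 (1.23) were higher in replicate 2, and the clock activator Arntl (-1.40) was lower. Both medians were above 0 under each of the 4 scales run.

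The erythroid list had a median of -1.60 (range -0.13 to 0.13) with 7 of 7 genes called, the white adipocyte list -1.29 over 4 genes (range -0.18 to 0.16) with 3 called, and the brown adipocyte list -1.32 over 5 (range -0.20 to 0.20) with 3 called. Adjusted over the list alone, the counts were 7, 3 and 3. In white fat these were the hormone adiponectin, Adipoq (-1.33), and the lipid droplet genes Plin1 (-1.79) and Cidec (-1.24), while Cfd was at -0.25. In brown fat they were Ucp1, Elovl3 and the deiodinase Dio2 (-1.32), while Cidea was at -0.88 and Ppargc1b at 0.24. All 3 list medians were below 0 under each of the 4 scales, and Cidec missed 2-fold with spike-in counts (-0.998).

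Smaller shifts relative to matched random lists, with no member called, also none adjusted over the list alone, were seen for 6 further lists. Mitochondrially encoded proteins lay above the range (0.19, range -0.08 to 0.05), with mt-Co1 at 0.09 and mt-Co2 at -0.43, against 0.08 and 0.08 in the second quantification. Ventricular markers also lay above it (0.15, range -0.13 to 0.11), as did sarcomere genes (0.04, range -0.06 to 0.03), whose median lay below 0 with total counts as the scale. Cell cycle genes lay below the range (-0.34, range -0.20 to 0.24). Glycolysis (-0.13, range -0.07 to 0.05) and imprinted genes (-0.14, range -0.10 to 0.10) did too, and their medians turned positive with spike-in counts as the scale, which moved all genes alike. With TPM + 1 the imprinted list lay inside its random range. In total 11 of 33 lists stood apart. The 1.65 that would by chance holds only where the genes within a list vary independently, which was not tested.

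The other 22 lists lay within their random ranges, among them the cardiomyocyte (0.02), fibroblast (0.01), endothelial (-0.05), smooth muscle (-0.06), pericyte (0.003) and macrophage (-0.09) markers. Calcium handling (-0.06), fatty acid oxidation (0.01), the nuclear-encoded respiratory chain (-0.05), heat shock (-0.03) and cardiac transcription factor genes (0.04) were within range as well. Among members called in such lists were the atrial growth factor Bmp10, lower at -1.08 (95% counting interval -1.17 to -0.98), and the interferon-induced gene Rsad2, lower at -1.08 (95% counting interval -1.28 to -0.89). The atrial, interferon response and Schwann and neuronal lists had 1 call each, and 1 each adjusted over the list alone, and with spike-in counts as the scale Bmp10 (-0.83) and Rsad2 (-0.84) missed 2-fold. Lists with fewer than 3 genes at a summed count of 50 were not compared; these were the Y-linked, T cell, neutrophil, mast cell, skeletal muscle, lung epithelium, thymocyte and hepatocyte lists.

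**Figure D4:**
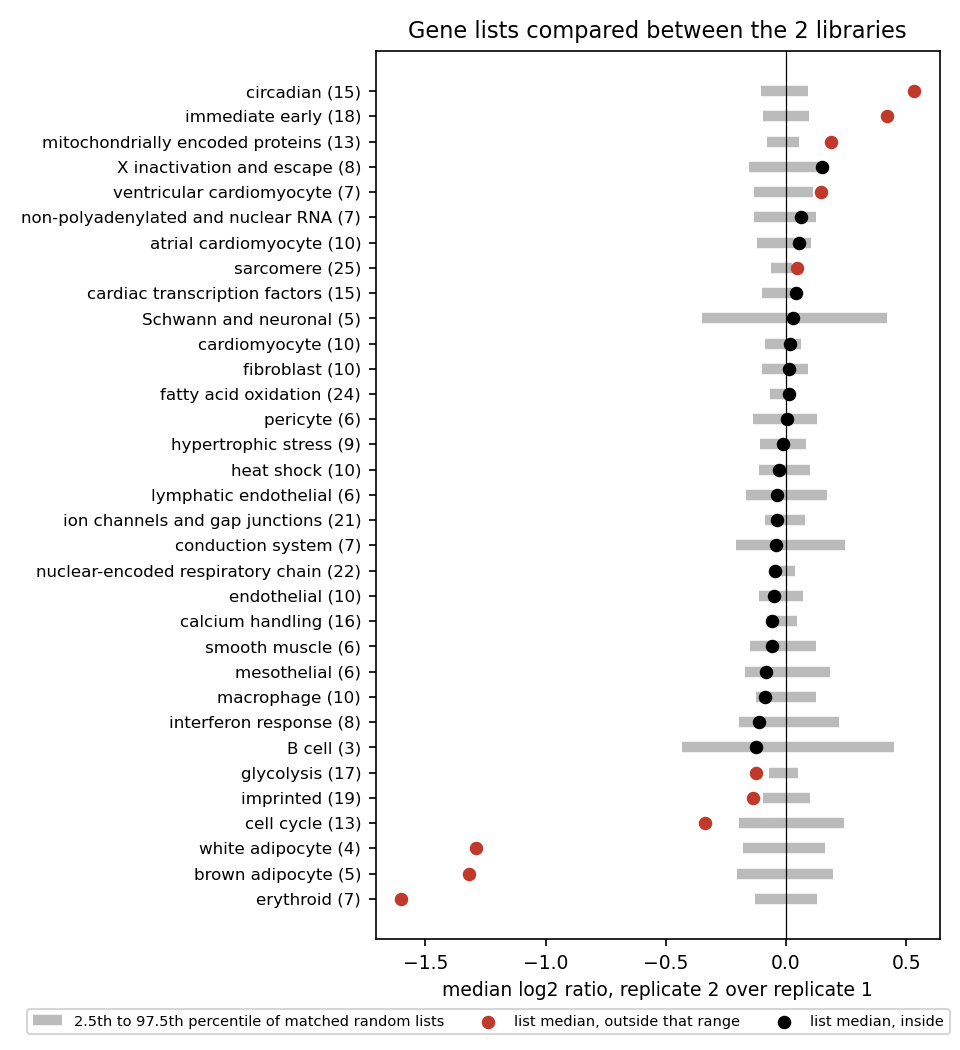
Median log2 ratio of replicate 2 over replicate 1 for each gene list (x axis; number of genes in parentheses), with grey bars for the central 95% of matched random lists. Erythroid (-1.60), brown adipocyte (-1.32) and white adipocyte (-1.29) lists lie far below their bars and circadian (0.53) and immediate early (0.42) lists above theirs.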

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

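The annotation entries named only by a number, which no comparison used, held a summed expected count of 3.89 in replicate 2 and 2 in replicate 1. The value of replicate 2 lies above the limit of 3 counts that a count of 0 allows, which is why it is listed. Of 26248 such entries, 3 had a count in either library, and no explanation was tested. Samples far from the others and differences between groups could not be looked for in a single group of 2.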

How the results depend on the processing

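The settings that ask for calls in both quantifications, for list members alike in both and for pseudogene reads in the mitochondrial share were chosen after seeing the data. No paired analysis was possible because the study holds 1 group. A quasi-likelihood model could not be fitted with 1 library a side. Leaving out a library gives no value for the comparisons of the 2 libraries. With 1 library alone, detected genes numbered between 12326 and 12403, and the counts of 26 pairs and 17 genes with a shared leading transcript did not move.

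The count of detected genes stayed within 1.5 times under 6 of 7 other settings and was 7668 at a TPM minimum of 5, which is stricter by construction. The correlation of the libraries was 0.975 with a pseudocount of 0.1, 0.995 without a filter, 0.985 at a mean TPM of at least 10 and 0.988 in the second quantification. Called genes numbered 475 at a 1.5-fold threshold, 135 when both quantifications had to call them and 118 when they also had to be protein-coding, against 210. With spike-in counts as the scale, 33.2% of 250 calls were lower in replicate 2 against 64.3% with TMM. This scale raised all genes alike, by 0.24 on the log2 scale. Lists standing apart numbered between 11 and 13, and scales cannot change which lists stood apart, since they move random lists too. Of the 11 lists, 10 stood apart under all 6 settings, though the size factor and spike-in scales among these settings could not change that. The X inactivation and cardiac transcription factor lists also stood apart in some settings, and the imprinted list lay inside its range with TPM + 1 (-0.10).

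Of the 42 called genes under the naming rule, 10 had under 50 summed counts in the second quantification and were not compared there. The counts of Chtf8 (0.348 and 41.5) and Hist1h2ah (10.3 and 30.1), 2 of these 10, rose there and fell in the first. Where compared, 1700047I17Rik2 (-8.45) and Gm20388 (-0.33) turned direction in the second quantification, and the cause was not tested. Compared genes stayed past the threshold in the same direction in 274 comparisons with another setting, and lost it in 8, 4 of them with spike-in counts. Size factors, other minimum counts and the exact test left the ratios nearly unchanged, so these comparisons are not independent checks. Pairs over 50% numbered 25 by expected counts and 25 in the second quantification, against 26. Leading transcripts were shared by 7 genes when a share of 50% was required in both. Taken over TPM, the class shares were 33.4% for mitochondrial genes, 0.763% for spike-ins, 2.401% for haemoglobin and 45.8% for the 10 highest genes, because TPM divides by length. The mitochondrial share of counts was 33.3% with the 4 pseudogenes added. Genes under 50 summed counts were compared only in the settings with a minimum of 10 or none, which called 311 and 297 genes.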

Other observations

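The tests on the sum of Gm42418 and Gm26917 and on all compared white adipocyte genes were chosen only after the result was seen. In a second adipocyte list, written before its values were seen and tested as a group, the fatty acid synthase Fasn had 83.7 TPM in replicate 1 and 23.7 in replicate 2 (log2 ratio -1.75), the desaturase Scd1 109 and 28.3 (-1.82), and the elongase Elovl6 had a log2 ratio of -1.90. Genes outside every list were chosen after their values were seen and were not tested as groups. The citrate-cleaving enzyme Acly (-1.22), the acetyl-CoA carboxylase Acaca (-1.24), the citrate carrier Slc25a1 (-1.24), Thrsp (-1.38) and the glycerol phosphate enzyme Gpd1 (-1.55) were also lower. The insulin receptor substrate Irs2 (1.57) and the kinase Sik1 (1.15) were higher. In the fixed fatty acid oxidation list, Pdk4 was at 0.77 and Ucp3 at 0.61, neither reaching 2-fold. The iron uptake receptor Tfrc (-1.50), the mitochondrial iron carrier Slc25a37 (-1.43), Bpgm (-1.23) and Tent5c (-1.50) were lower, as were the endothelial transcription factors Sox18 (-1.22) and Sox7 (-1.14).

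Lower adipocyte genes in replicate 2 may reflect a smaller amount of attached adipose tissue. The second list of 12 adipocyte genes had 9 that could be compared, all lower, with a median log2 ratio of -1.82 (matched random lists -0.15 to 0.14) and 7 called, Otop1 at -2.52 and Adrb3 at -2.10 among them. Over 4 scales the white adipocyte median lay between -1.36 and -1.04. A scale moves all genes alike, so its choice could not change the gap to matched random lists, and this test decided nothing about the cause of that gap. A lower thermogenic programme in the same amount of adipose tissue cannot be told apart: the 4 white adipocyte genes compared had a median of -1.29, but they are few and Cfd (-0.25) stayed near 0, as that explanation asks. One proportional loss does not cover every gene, as Ucp1 (-2.67) lay below Adipoq (-1.33) while Aqp7 (-0.14) and Me1 (-0.04) were near 0. Other tissues also express at least Fasn, Scd1, Elovl6, Pck1 and Me1 of the second list, so the feeding state of the animals stays open too, and the design names no biological explanation to test.

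The higher Gm42418 was not specific to a quantification, since its log2 ratio was 2.58 in the second one. A different division of reads with the neighbouring Gm26917 as the whole cause is argued against by the sum of both, with a log2 ratio of 1.07, and Gm26917 itself was at 0.21. More ribosomal RNA left in the library remains a candidate explanation that cannot be told apart from others. Of other ribosomal RNA features only CT010467.1, which lies opposite Gm42418 on the other strand and is annotated as ribosomal RNA, had a summed count of at least 50, with a log2 ratio of 2.87. This is the direction the explanation asks for, but it is a single feature at the same place as Gm42418, while AY036118 had no count in either library. Lars2 was higher as well, at 4.48, and no biological explanation was tested.

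The clock genes differed in a way that may reflect a different clock phase of the 2 animals at collection. Outside the list, 7 clock-controlled genes were each given the sign written for a later phase (Usp2 and Tspan4 higher, Nfil3 lower, for example). Their median signed log2 ratio was 0.29 (matched random lists -0.16 to 0.16), with 6 of 7 in the direction of that sign. A difference shared by all transcription factors is argued against by the cardiac transcription factor list. Its median absolute log2 ratio was 0.10 against 0.59 for the clock list. A difference in part of them stays open, since the immediate early list, which holds factors such as Fos, also stood apart (median 0.42). Collection times are not given in the sources used here. Without them, and with signs written for a later phase only, a later phase in replicate 2 cannot be told apart from an earlier one. The phase stays a hypothesis, and the design gives no biological explanation to test.

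The counts of mouse genes per spike-in count were 187 in replicate 1 and 233 in replicate 2. First and second quantification correlated across genes with Pearson r = 0.871 over 13098 genes and 0.972 over 11645 protein-coding genes, genes not being independent replicates. At a mean TPM of at least 10 in the first and under 1 in the second quantification stood 187 genes, among them Rn7s1, Rn7sk, mt-Atp8 and the ribonuclease RNA Rmrp.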
